A study of Arabidopsis thaliana with 8 samples.

How the data were processed

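RNA came from rosette leaves of WT and DLK2-OE1 plants, 4 libraries each. Per the labels' protocols, mRNA was captured with oligo(dT) beads, made into cDNA with a NEBNext Ultra kit and sequenced on an Illumina NovaSeq. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1, RSEM, DESeq2, edgeR and the TAIR10 build, with no order or role. The strand setting and the annotation release are not given in the sources used here, so genes that overlap on opposite strands, and near-identical paralogs, are uncertain.

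The deposited tables give for each library a whole-number count and an FPKM value per gene, per the file headers, over 27634 rows. Whether the deposited counts are whole reads or rounded estimates is not given in the sources used here. For 9592 genes with over 200 counts in all libraries, each gene's FPKM to count ratio was divided by its ratio in WT replicate 1. Of these quotients, 96.6% lay within 1% of a single factor per library. Gene length cancels in them, so they show a shared scaling per library and do not test length scaling. Of the rows, 26719 matched locus tags of the TAIR10.1 annotation, from which gene names and coordinates were taken, and 218 carry names of the kind StringTie gives to assembled loci, whose positions are not used here. Total counts per library were 18097159, 22139801, 21339007 and 19641535 for WT and 18461205, 19385026, 18894544 and 18576287 for DLK2-OE1. Chloroplast genes held at most 0.0213% of counts. Replicate pairs differed by far more than sampling noise, with chi-square per degree of freedom from 11.4 to 108.1, so each library counted once.

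Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by genotype, TMM normalization, estimateDisp, glmQLFit with robust estimation and glmQLFTest, with Benjamini-Hochberg adjustment over 18155 genes and a threshold of 0.05. The common biological coefficient of variation was 0.222. CPM values are TMM-normalized. The standard error is the log2 fold change divided by the square root of the quasi-likelihood F. For DLK2 the difference in mean CPM was also tested by an exact two-sided permutation test in SciPy 1.17.1. The median log2 fold change of all genes was near 0 under each scaling used.

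Before the data were examined, 38 gene lists covering hormones, metabolism, photosynthesis, clock, nutrition, growth and cell types were written down, and 11 loci stand in more than 1 list. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Named genes followed a rule also fixed then. It takes DLK2 and the members of the strigolactone and karrikin signalling list. It takes the 12 largest increases and the 12 largest decreases among genes past the threshold with a 2-fold change, at least 5 CPM in the higher group, no overlap between genotypes and a gene symbol. It takes up to 4 members past the threshold per list. The values of 1 gene that the rule takes are not reported here.

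Alternatives were DESeq2 size factors, no filter, at least 10 counts in 4 libraries, organelle genes left out, a replicate block, DESeq2 1.42.0, limma-voom, limma-trend on log2 FPKM with pseudocounts of 1, 0.1 and 0.01 for genes with FPKM of at least 1 in 4 libraries, glmTreat against 1.5-fold, fry, an estimated inter-gene correlation and the omission of each library. The limma-trend fit with a pseudocount of 1 and the omission of DLK2-OE1 replicates 1 and 2 together were added after seeing the data.

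The procedure was tested on simulated counts for this comparison with 200 of 18057 genes changed. It recovered 67.7% of 2-fold and 93.9% of 4-fold changes, with 9 false calls among 169. The 200 changed genes were drawn only from genes above a minimum mean CPM, so the recovery does not cover genes of lower level. The simulated counts were drawn gene by gene, with the same dispersion in both genotypes and no variation shared between genes. The real libraries do share such variation, so these rates need not hold for them.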

Results

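Transcripts were measured in rosette leaves of 24-day-old Arabidopsis thaliana, with 4 libraries from the wild type (WT) and 4 from DLK2-OE1, a line that overexpresses DLK2. DLK2 (DWARF14-LIKE 2) is an α/β hydrolase related to D14, the strigolactone receptor, and to KAI2, the receptor needed for karrikin responses. Plants had spent 11 days on plates and 13 days on soil. Library totals ranged from 18097159 to 22139801 counts. The labels do not say whether replicates were separate plants or pools, so p-values measure only the spread between these libraries, which may be technical. The single comparison of the design asks which leaf transcripts differ between this overexpressing line and WT. All overexpressing libraries come from a single line, DLK2-OE1. A change caused by DLK2 therefore cannot be told apart from other differences between that line and WT.

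DLK2 (AT3G24420) was higher in all 4 DLK2-OE1 libraries than in any WT library. Its normalized level was 73.1 ± 10.1 CPM in WT (SD, n = 4) and 138 ± 13.2 CPM in DLK2-OE1 (SD, n = 4), a 1.89-fold difference. Raw counts were 1025, 1496, 1712 and 1438 in the WT libraries and 2400, 3503, 2553 and 2572 in the DLK2-OE1 libraries. The log2 fold change was 0.92 (SE 0.12), with an adjusted p of 0.0178 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. An exact two-sided permutation test over the 70 assignments of libraries gave p = 0.0286, the smallest p this design allows. In the TAIR10.1 annotation the gene lies on the minus strand of chromosome 3 from 8862813 to 8865239. Its 2 exons run from 8864495 to 8865239 and from 8862813 to 8863543, and its coding parts from 8864495 to 8864883 and from 8863111 to 8863543, the rest being untranslated. Counts do not separate transcripts of the endogenous gene from those of a transgene. The adjusted p rose to 0.067 without WT replicate 1, 0.0548 without WT replicate 3 and 0.0574 without DLK2-OE1 replicate 1, at log2 fold changes of 0.83, 0.99 and 0.97.

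**Figure D1:**
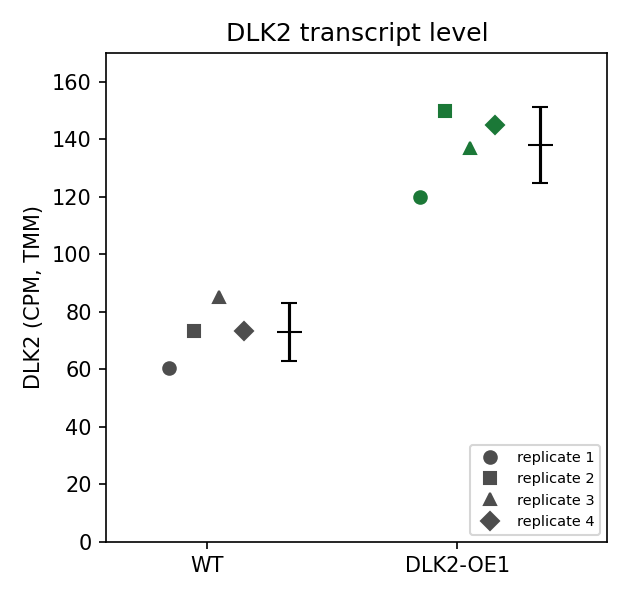
DLK2 level in CPM (vertical axis, from 0) for each library of WT and DLK2-OE1 (horizontal axis), with marker shape giving the replicate number and the black bar the mean and SD of 4 libraries. The WT libraries lie between 60.4 and 85.1 CPM and the DLK2-OE1 libraries between 120 and 150 CPM.

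The meristem homeobox genes KNAT1, STM and KNAT6, 3 of 8 xylem markers and 4 of 22 cell cycle genes rose in DLK2-OE1, while 4 of 24 jasmonate genes and the flowering signals FT and TSF fell. By camera, the xylem, cell cycle and jasmonate lists passed with a preset correlation only, each with adjusted p = 0.512 with an estimated correlation. Of 18155 genes tested with edgeR, 670 passed an adjusted p of 0.05, of which 384 were higher and 286 lower in DLK2-OE1. Among these, 360 changed at least 2-fold, 280 of them higher and 80 lower. The 4 libraries of one genotype lay entirely outside the range of the other at 2753 tested genes, or 15.2%, against 2.86% by chance. The smallest adjusted p among all genes was 0.0111, so the calls lie close to the threshold. The count was 13 without WT replicate 1, 118 without WT replicate 2, 14 without DLK2-OE1 replicate 1, 232 without DLK2-OE1 replicate 2, 1368 without DLK2-OE1 replicate 3 and 2191 without DLK2-OE1 replicate 4. Without WT replicate 3, edgeR called 0 genes, with 3599 at an unadjusted p under 0.05, where limma-voom called 0 and DESeq2 1426. On all libraries limma-voom called 265 genes and DESeq2 2782. Of the 65 named genes past the threshold, 1, 19, 0 and 42 passed without WT replicates 1 to 4 and 3, 34, 61 and 65 without DLK2-OE1 replicates 1 to 4. All 65 kept their direction in each omission. Their libraries do not overlap between genotypes, so this could hardly come out otherwise and does not show stability.

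The first principal component held 60.3% of the variance, with WT libraries at -47.2, -27.7, -47.5 and -29.6 and DLK2-OE1 libraries at 61.5, 87.4, 11.2 and -8.2. Of the 280 genes at least 2-fold higher in DLK2-OE1, 239 had their highest level in replicate 2 and 30 in replicate 1. The median ratio of these genes to the WT mean was 4.32, 5.85, 2.41 and 2.14 in DLK2-OE1 replicates 1 to 4. For the 80 genes at least 2-fold lower it was 0.396, 0.29, 0.484 and 0.426. With replicates 1 and 2 both left out, an alternative chosen after seeing the data, edgeR called 60 genes, 43 higher and 17 lower, of which 57 were among the 670.

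**Figure D2:**
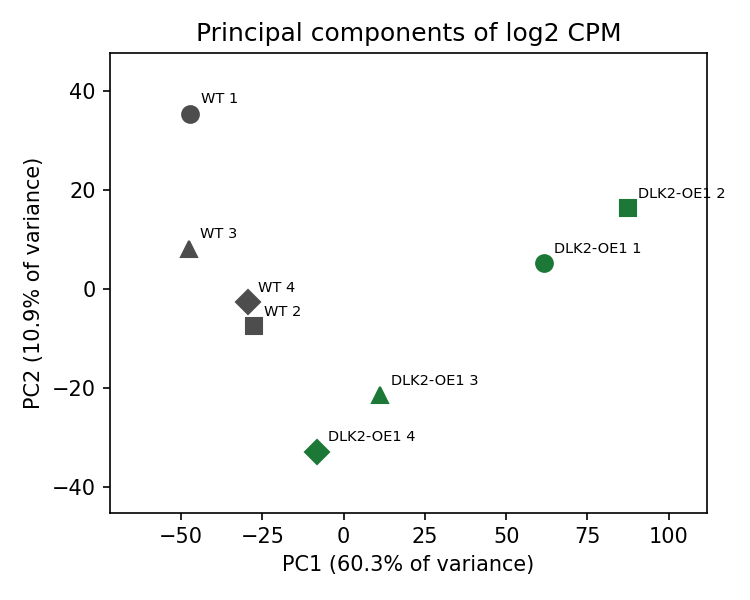
First and second principal components of log2 CPM (axes, in component units, with the percent of variance each holds) for the 8 libraries, coloured by genotype. DLK2-OE1 replicates 1 and 2 lie at 61.5 and 87.4 on the first component, away from replicates 3 and 4 at 11.2 and -8.2.

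The largest increases were in genes almost silent in WT leaves. KNAT1 (AT4G08150, chromosome 4, 5147699 to 5151159) and STM (AT1G62360, chromosome 1, 23058582 to 23062063), homeobox genes that maintain shoot meristems, had 13.4 ± 11.7 and 10.6 ± 9.41 CPM in DLK2-OE1 against 0.123 ± 0.246 and 0.135 ± 0.27 CPM in WT (SD, n = 4 each). Both had 0 counts in WT replicates 1, 3 and 4, with 10 counts for KNAT1 and 11 for STM in WT replicate 2. Their edgeR adjusted p was 0.0229 and 0.0318. The related KNAT6 reached 5.16 ± 4.53 CPM against 0.344 ± 0.155 CPM (adjusted p = 0.0374). The peroxidase gene PER64 (AT5G42180) gave 510, 1361, 115 and 657 counts in the DLK2-OE1 libraries and 0, 1, 3 and 0 in WT. SUS4, a sucrose synthase gene, gave 170, 576, 81 and 22 counts against 0, 1, 0 and 3. Fitted log2 fold changes for genes this close to 0 in WT, such as 9.10 (SE 0.99) for PER64, depend on the prior count. The remaining genes among the 12 largest increases were CYP96A15, scpl31, ABCB15, GH9B13, FLA12, UCC2 and NEK4, at log2 fold changes from 6.49 to 3.44.

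MRD1 (AT1G53480) had the largest decrease among the named genes, a log2 fold change of -6.20 (SE 0.99). It fell from 7.88 ± 5 CPM in WT to 0.103 ± 0.142 CPM in DLK2-OE1 (SD, n = 4 each, edgeR adjusted p = 0.0209). CAX3, a vacuolar cation exchanger gene, fell from 18.8 ± 3.59 to 5.73 ± 1.05 CPM, a log2 fold change of -1.71 (SE 0.18, adjusted p = 0.0111). SEP3, a floral MADS-box gene, fell from 23.7 ± 11.9 to 4.2 ± 3.03 CPM (adjusted p = 0.0445). The other 9 of the 12 largest decreases, GSTU1, TBL26, CSLB03, CORI3, HSP90.1, FT, NDB2, NGA1 and NIT4, had log2 fold changes between -2.09 and -1.45.

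**Figure D3:**
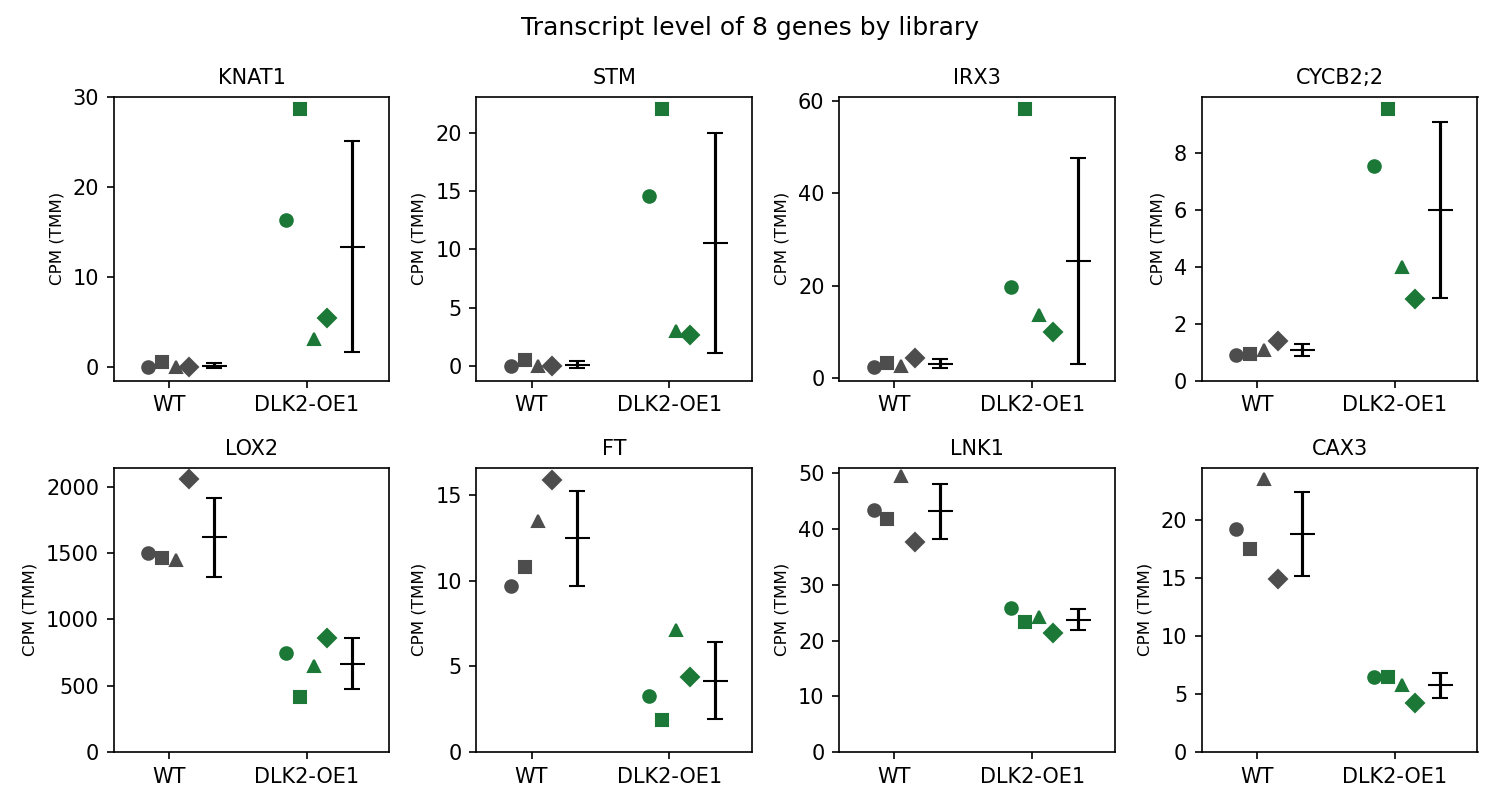
Level in CPM (vertical axes, linear) of 8 named genes in each library of WT and DLK2-OE1, with marker shape giving the replicate number and black bars the mean and SD of 4 libraries. KNAT1, STM, IRX3 and CYCB2;2 are highest in DLK2-OE1 replicate 2, and LOX2, FT, LNK1 and CAX3 are lower in each DLK2-OE1 library than in each WT library.

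In the strigolactone and karrikin signalling list, 2 of 11 tested members rose and 9 did not pass. MAX2, the F-box protein shared by both pathways, rose from 39.7 ± 5.22 to 54.5 ± 2.28 CPM (SD, n = 4 each), a log2 fold change of 0.46 (SE 0.10, edgeR adjusted p = 0.0469). SMXL5 rose from 3.12 ± 0.773 to 9.87 ± 5.37 CPM (log2 fold change 1.66, SE 0.37, adjusted p = 0.0461). The receptor genes did not pass: D14 had a log2 fold change of -0.37 (SE 0.19, adjusted p = 0.243) and KAI2 of -0.35 (SE 0.13, adjusted p = 0.135). Log2 fold changes of the other members of the SMAX1 and SMXL family were -0.49 for SMAX1, -0.04 for SMXL2, 0.70 for SMXL3, 1.29 for SMXL4, 0.45 for SMXL6, 0.27 for SMXL7 and 1.36 for SMXL8, at adjusted p from 0.0737 to 0.876. With DESeq2, SMAX1 (adjusted p = 0.0374), SMXL3 (0.0191), SMXL4 (0.0277) and SMXL8 (0.0327) passed, and SMXL8 also passed without DLK2-OE1 replicate 4 (0.0474). Adjusted over the list alone, 6 members were higher and 2 lower. The list as a whole did not pass the camera test (adjusted p = 0.127), nor did the list of strigolactone and karrikin response genes (0 of 9 members, or 4 higher adjusted over the list alone, adjusted p = 0.0929, against 0.0269 with no filter). Of 4 tested strigolactone biosynthesis genes 0 passed.

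Of 22 tested cell cycle members 4 rose and 18 did not pass, with 21 positive fold changes and a median log2 fold change of 1.65, and 19 were higher adjusted over the list alone. The mitotic cyclin gene CYCB2;2 rose from 1.07 ± 0.222 to 5.97 ± 3.09 CPM (SD, n = 4 each, edgeR adjusted p = 0.0209), and AUR2, CDKB1;1 and CDKB2;2 rose 6.30-fold, 5.12-fold and 2.59-fold. The camera test gave an adjusted p of 1.61e-07 with its preset correlation, and adjusted p = 0.512 with an estimated correlation. Relative to the WT mean, the list's median was 2.00 and 2.38 log2 units in DLK2-OE1 replicates 1 and 2 and 0.72 and 0.37 in replicates 3 and 4.

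Of 8 tested xylem markers 3 rose and 5 did not pass, while all 8 were higher adjusted over the list alone, with a median log2 fold change of 1.68. IRX3, CESA8 and CESA4, the cellulose synthases of secondary walls, rose from 3.13 ± 0.895, 3.58 ± 1.6 and 8.08 ± 1.51 CPM to 25.3 ± 22.3, 20.4 ± 15.5 and 27.9 ± 19.5 CPM (SD, n = 4 each, edgeR adjusted p = 0.0328, 0.0411 and 0.0495). The camera adjusted p was 7.77e-05, and adjusted p = 0.512 with an estimated correlation. The list's median per library was 1.91, 2.71, 0.97 and 0.54 log2 units above the WT mean in DLK2-OE1 replicates 1 to 4, and 0.64 in WT replicate 4. Phloem markers had a median log2 fold change of -0.29 and missed the camera threshold (adjusted p = 0.0627, passing without WT replicate 2 at 0.0417, without DLK2-OE1 replicate 4 at 0.0403 and with no filter at 0.0426), with 1 of 9 members, SWEET13, lower at 0.701 ± 0.0747 CPM against 2.82 ± 1.18 CPM in WT (SD, n = 4 each, edgeR adjusted p = 0.0219). Adjusted over the list alone, 1 phloem marker was higher and 1 lower. Neither guard cell markers (0 of 9, camera adjusted p = 0.982) nor epidermis and trichome markers (0 of 7, camera adjusted p = 0.0929) passed on all libraries. The epidermis and trichome list passed without WT replicate 2 (0.00543) or 3 (0.0336), without DLK2-OE1 replicate 4 (0.0282) and with no filter (0.0329). Of 4 tested shoot apex and flower markers STM rose and SEP3 fell, with a median log2 fold change of -1.87, and 1 was higher and 3 lower adjusted over the list alone, and 1 root marker was tested, which did not pass.

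Of 26 tested cell wall loosening members 6 rose and 20 did not pass, 12 being higher and 1 lower adjusted over the list alone. XTH4, a xyloglucan-modifying enzyme gene, rose from 413 ± 50.4 to 806 ± 61.9 CPM (SD, n = 4 each), a log2 fold change of 0.97 (SE 0.13, edgeR adjusted p = 0.0178). XTH8, EXLA2 and EXLA3 rose 2.53-fold, 1.88-fold and 3.64-fold. The camera adjusted p was 6.64e-05, and adjusted p = 0.361 with an estimated correlation. Its median in DLK2-OE1 replicates 1 to 4 was 0.71, 0.81, 0.62 and 0.45 log2 units above the WT mean. In the leaf growth and form list 3 of 21 members rose (ARGOS, KNAT1 and STM) and 2 fell, TCP2 at a log2 fold change of -0.65 (SE 0.11, adjusted p = 0.0231) and TCP3 at -0.69 (SE 0.15, adjusted p = 0.0452). ARGOS, a promoter of organ growth, rose from 0.405 ± 0.11 to 2.81 ± 0.865 CPM (adjusted p = 0.0147). Adjusted over the list alone, 9 were higher and 4 lower. This list passed camera at an adjusted p of 0.0199, with adjusted p = 0.54 with an estimated correlation, and missed it without WT replicate 4 (0.0687) and without DLK2-OE1 replicate 2 (0.0521).

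Of 15 tested wax and cutin genes 3 rose: CER1, which acts in alkane synthesis, from 25.5 ± 13.8 to 90.2 ± 24.8 CPM (SD, n = 4 each, edgeR adjusted p = 0.0361), CER4 4.84-fold and CYP96A15, which had 0 counts in WT replicates 1, 3 and 4. The same 3 were higher adjusted over the list alone. The list passed camera at an adjusted p of 0.0199, with adjusted p = 0.512 with an estimated correlation, and missed it without WT replicate 4 (0.0668) and without DLK2-OE1 replicates 3 (0.102) or 4 (0.0659).

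Of 24 tested jasmonate genes 4 fell and 20 did not pass, with 20 negative fold changes in all, and 12 were lower adjusted over the list alone. LOX2 (AT3G45140, chromosome 3, 16525245 to 16529352), AOS and AOC2, which act in succession in jasmonate synthesis, fell from 1620 ± 297, 411 ± 48.1 and 415 ± 54.4 CPM to 666 ± 189, 216 ± 36.8 and 216 ± 41.9 CPM (SD, n = 4 each, edgeR adjusted p = 0.0328, 0.0234 and 0.0303). The repressor gene JAZ7 fell with a log2 fold change of -1.31 (SE 0.27, adjusted p = 0.0425). The camera adjusted p was 1.48e-05, and adjusted p = 0.512 with an estimated correlation. The list's median was -0.63, -0.75, -0.32 and -0.52 log2 units from the WT mean in DLK2-OE1 replicates 1 to 4.

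For auxin 3 of 28 members rose, among them IAA4 from 61.1 ± 6.81 to 94.5 ± 2.41 CPM (SD, n = 4 each, edgeR adjusted p = 0.02) and IAA19 1.73-fold, and the biosynthesis gene TAA1 fell (log2 fold change -0.83, SE 0.18, adjusted p = 0.0438). Adjusted over the list alone 7 were higher and 1 lower. The camera adjusted p was 0.0484, with adjusted p = 0.512 with an estimated correlation, and the call was lost without WT replicates 1 (0.0565) or 3 (0.0627) and DLK2-OE1 replicates 3 (0.209) or 4 (0.161), with DESeq2 size factors (0.0519) and with no filter (0.104). The ethylene receptor genes ETR2, ERS2 and ERS1 rose 8.71-fold, 2.11-fold and 1.47-fold (3 of 13 members, 4 higher adjusted over the list alone, camera adjusted p = 0.143). In the cytokinin list CKX6 and ARR5 rose 2.85-fold and 1.95-fold (2 of 13, or 6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0547, which passed without WT replicate 2 at 0.0108 or 3 at 0.0245 and without DLK2-OE1 replicate 2 at 0.03, 3 at 0.0474 or 4 at 0.0421), in the gibberellin list GASA4 rose 3.31-fold (1 of 18, or 4 higher adjusted over the list alone, camera adjusted p = 0.762) and in the brassinosteroid list DWF1 rose 1.76-fold (1 of 17 on either adjustment, camera adjusted p = 0.258). For abscisic acid 1 of 24 members fell, the catabolic gene CYP707A2, from 1.52 ± 0.49 to 0.413 ± 0.195 CPM, and 1 was lower adjusted over the list alone. The list passed camera at 0.0127, with adjusted p = 0.512 with an estimated correlation.

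FT (AT1G65480, chromosome 1, 24331373 to 24333999), which encodes the mobile flowering signal, fell from 12.5 ± 2.8 to 4.17 ± 2.23 CPM (SD, n = 4 each, edgeR adjusted p = 0.0467), and its relative TSF from 0.883 ± 0.227 to 0.278 ± 0.103 CPM (adjusted p = 0.0467). MAF5, a floral repressor, rose from 5.36 ± 2.57 to 17.7 ± 5.23 CPM (adjusted p = 0.0487). The other 12 of 15 flowering genes did not pass, 3 were higher and 5 lower adjusted over the list alone, and the list missed the camera threshold (adjusted p = 0.261). Of 20 clock genes LNK1 fell from 43.2 ± 4.93 to 23.7 ± 1.86 CPM (adjusted p = 0.0147) and CDF1 from 14.4 ± 1.72 to 8.33 ± 0.622 CPM (adjusted p = 0.0192), and 7 were lower and 1 higher adjusted over the list alone. The clock list passed camera at 0.00336, with adjusted p = 0.512 with an estimated correlation. SPA1, a repressor of light signalling, fell with a log2 fold change of -0.74 (SE 0.11, adjusted p = 0.02), alone among 21 light and shade genes, of which 2 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.21).

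Several lists passed camera with 0 or 1 members past the threshold. Adjusted over the list alone, 4 of 12 phosphate starvation genes and 3 of 13 chlorophyll synthesis genes were lower, against 0 for light harvesting, salicylate and immunity, cold, iron and aliphatic glucosinolates. Light harvesting and carbon fixation genes had 23 negative fold changes of 23 and a median of -0.38 (camera adjusted p = 6.64e-05, adjusted p = 0.54 with an estimated correlation), at -0.53, -1.14, -0.15 and 0.07 log2 units from the WT mean in DLK2-OE1 replicates 1 to 4, where xylem markers stood at 1.91, 2.71, 0.97 and 0.54 and cell cycle genes at 2.00, 2.38, 0.72 and 0.37. Chlorophyll synthesis genes had 13 of 13 negative (0.00128, and adjusted p = 0.522 with an estimated correlation), and salicylate and immunity genes 20 of 21 (0.000858, and adjusted p = 0.54 with an estimated correlation). Camera also placed lower the lists for cold (0 of 14 members, 0.00542, and adjusted p = 0.512 with an estimated correlation), phosphate starvation (0 of 12, 0.00495, and adjusted p = 0.512 with an estimated correlation), iron homeostasis (0 of 17, 0.0271, and adjusted p = 0.512 with an estimated correlation) and heat shock. In the heat shock list 1 of 10 members, HSP90.1, fell 3.05-fold (6 lower adjusted over the list alone, camera adjusted p = 0.0147, adjusted p = 0.525 with an estimated correlation). Its median was 0.75, -0.82, 0.23 and -0.25 log2 units from the WT mean in WT replicates 1 to 4 and -0.58, -0.70, -0.70 and -0.69 in DLK2-OE1 replicates 1 to 4. Aliphatic glucosinolate genes were placed higher with 0 of 17 members past the threshold (0.0147, and adjusted p = 0.617 with an estimated correlation).

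In all, camera placed 7 lists higher and 10 lower out of 35 with at least 5 tested members, and 0 of the 17 held with an estimated correlation. The medians per library of the 2 genotypes did not overlap for 5 of the 17 (cell cycle, cell wall loosening, jasmonate, clock and phosphate starvation) and overlapped for the other 12. The heat shock call was lost without WT replicate 1 (0.0531), the iron call without WT replicate 1 (0.0878) or DLK2-OE1 replicate 2 (0.0521), and the aliphatic glucosinolate call without WT replicate 2 (0.0876) or DLK2-OE1 replicates 1 (0.0535) or 2 (0.108). With DLK2-OE1 replicates 1 and 2 both left out, the calls were lost for light harvesting (0.276), cold (0.31), salicylate and immunity (0.137), abscisic acid (0.0836), the clock (0.0522), leaf growth (0.381) and aliphatic glucosinolates (0.524). The same omission brought sulfur deficiency (0.000946, lower), sugar starvation (0.0011, higher) and ethylene (0.0463, higher) past the threshold. The lists for flavonoids (0 of 14, camera adjusted p = 0.81), indole glucosinolates (0 of 9, 0.998), sugar starvation (0 of 13, 0.0968), nitrate (0 of 15, or 1 higher adjusted over the list alone, 0.804), sulfur deficiency (0 of 10, or 1 lower adjusted over the list alone, 0.233) and rapid touch responses (0 of 13, 0.139) did not pass on all libraries. Without DLK2-OE1 replicate 4 the touch list (0.000347, lower) and the flavonoid list (0.0466, higher) passed, and without DLK2-OE1 replicate 2 the sugar starvation list did (0.0132). In the leaf senescence list 1 of 16 members, the chlorophyll breakdown gene NYC1, fell 1.42-fold, 2 were lower adjusted over the list alone, and the list did not pass (0.143).

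**Figure D4:**
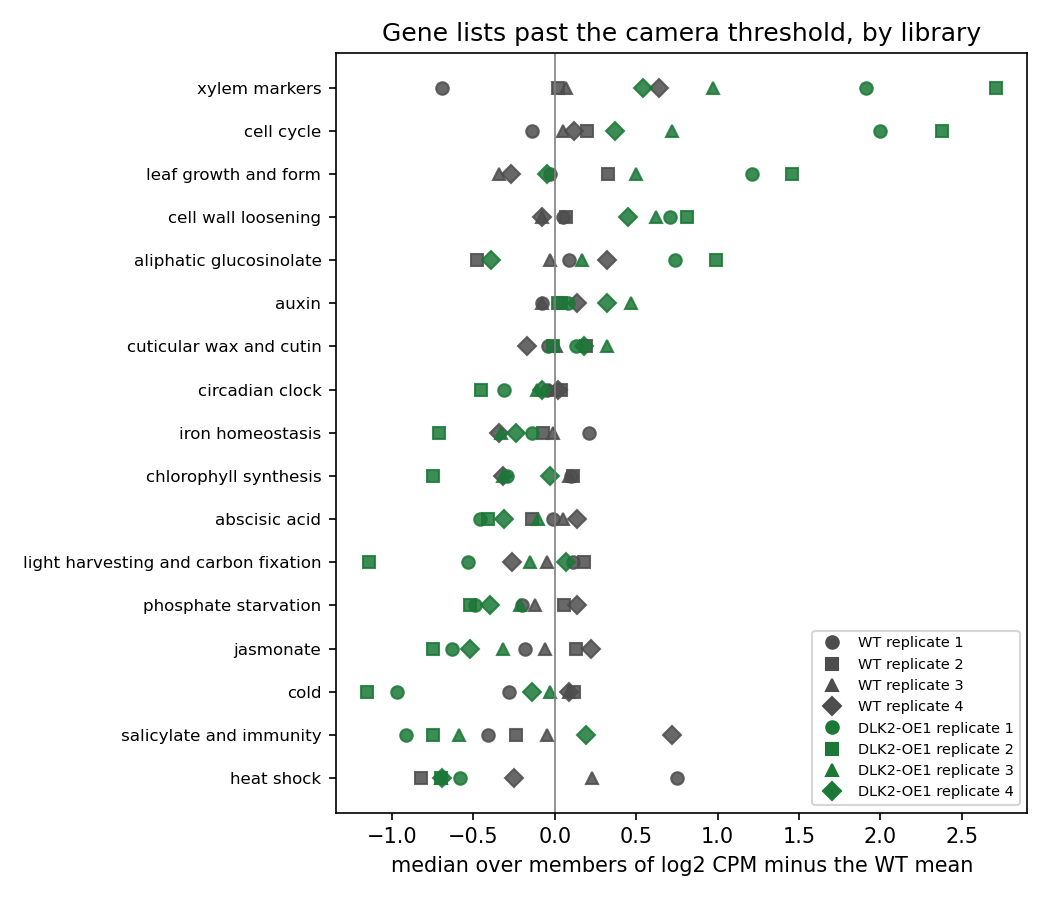
Median over list members of log2 CPM minus the WT mean (horizontal axis, log2 units) for the 17 lists past the camera threshold with a preset correlation (vertical axis), one marker per library. For cell cycle genes DLK2-OE1 replicates 1 and 2 lie at 2.00 and 2.38 and replicates 3 and 4 at 0.72 and 0.37.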

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

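Among 156 groups of 4 libraries examined, 14 held a library far from its 3 companions, where chance gives about 1 in 20 groups, or 7.8. No explanation was tested for these values. In WT replicate 2 KNAT1 was at 0.491 CPM, STM at 0.54 CPM and CYP96A15 at 0.639 CPM, each against 0 in the other WT libraries, with CER1 at 46.1 CPM and SMXL5 at 4.27 CPM also above the rest. In WT replicate 4 the highest values were 2060 CPM for LOX2, 487 CPM for XTH4, 23 CPM for SMXL6, 1.07 CPM for CDKB1;1 and 1.02 CPM for NEK4. Among DLK2-OE1 libraries, replicate 2 was lowest for AOC2 at 153 CPM and highest for CESA8 at 43.3 CPM, replicate 1 was highest for CER4 at 12.1 CPM and replicate 3 for HSP90.1 at 7.77 CPM.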

How the results depend on the processing

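The omission of DLK2-OE1 replicates 1 and 2 together and limma-trend on log2(FPKM + 1) were chosen after seeing the data. The cause of the changes given here was not tested, except that omissions leave fewer libraries. DLK2 kept its direction under every alternative, with log2 fold changes of 0.83 to 0.99 when single libraries were left out. All 670 genes kept their direction under each count-based alternative. For 660 of them the libraries did not overlap between genotypes, so leaving libraries out could hardly turn their direction.

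The number of genes changed was 5 with glmTreat (4 higher, 1 lower, 5 at least 2-fold), 265 with limma-voom (108, 157 and 121), 2782 with DESeq2 (1734, 1048 and 1341), 288, 340 and 335 with limma-trend on FPKM at pseudocounts of 1, 0.1 and 0.01 (170, 216 and 214 higher, 118, 124 and 121 lower, 110, 173 and 170 at least 2-fold), and 60 without DLK2-OE1 replicates 1 and 2 (43, 17 and 35). Leaving out single libraries gave 0 to 2191 genes, 0 to 1451 higher, 0 to 740 lower and 0 to 1274 at least 2-fold. DESeq2 size factors, no filter, the stricter filter and the omission of organelle genes gave 663, 670, 664 and 669 genes. The share of calls that were higher was 57.3% in the edgeR fit, 40.8% with limma-voom and 71.7% without DLK2-OE1 replicates 1 and 2. Among alternatives with any calls it ran from 30.8% of 13 calls without WT replicate 1 to 80.0% of 5 calls with glmTreat.

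With a replicate block, 245 genes changed (133 higher, 112 lower, 161 at least 2-fold), the camera adjusted p of the auxin list was 0.0611 and those of the cytokinin and phloem lists were 0.0446 and 0.0488. Of the 64 named genes past the threshold besides DLK2, 33 did not pass with the replicate block and 37 did not with limma-voom. Replicate numbers did not pair the libraries: correlations of same-numbered libraries' deviations ranged from -0.095 to 0.123, and 1 of 8 libraries correlated best with its own number.

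Of the 17 gene lists, 0 passed with an estimated correlation and 1 with fry, cell wall loosening. The first principal component held 70.4% of variance over the 1000 most variable genes.

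Directions turned only for values that had not passed, except for aliphatic glucosinolate genes. SMXL2 had log2 fold changes of 0.08, 0.09 and 0.09 on FPKM, -0.19 to 0.03 when single libraries were left out (0.03 and 0.02 without DLK2-OE1 replicates 1 and 2) and 0.16 without both, where SMXL7 was at -0.06. List directions turned at adjusted p of 0.121 (flavonoids), 0.524 (aliphatic glucosinolates), 0.982 (flowering), 0.355 (touch) and 0.645 (guard cell) without DLK2-OE1 replicates 1 and 2, and for flavonoids, indole glucosinolates, nitrate and guard cell markers also when some single libraries were left out. Over all such omissions their adjusted p ranged from 0.0466 to 0.868, 0.56 to 0.904, 0.514 to 0.977 and 0.582 to 0.913. Guard cell markers also turned with fry (0.989), no filter (0.692) and the replicate block (0.903), and indole glucosinolates with fry (0.989).

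Depth limits genes near 0 in WT, such as PER64 with 4 counts over the WT libraries, more than abundant genes such as LOX2.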

Other observations

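All tests in this part except the count of library splits were chosen after the results were seen. The exact permutation tests in this part shuffle genes between lists, so their p-values do not measure the spread between libraries. Among copper-linked genes, listed after the data were seen, 5 of 11 tested microRNA targets rose and 1 of 7 tested deficiency genes fell. The copper/zinc superoxide dismutase genes CSD1 and CSD2 and their copper chaperone CCS were higher in DLK2-OE1, at log2 fold changes of 1.58 (SE 0.29), 2.31 (SE 0.32) and 1.24 (SE 0.17) and edgeR adjusted p of 0.0321, 0.0178 and 0.0178. The copper transporter gene COPT2 was lower at -1.63 (SE 0.24, adjusted p = 0.0195), and the iron superoxide dismutase gene FSD1 was at -0.96 (SE 0.24, adjusted p = 0.0551). Members that did not pass include LAC13 at -0.14, COPT1 and COPT6 at -0.34 each and FRO4 at -0.58 (adjusted p = 0.335). Among product families of at least 10 tested genes, arabinogalactan proteins were in excess among higher genes (5 of 22, Fisher's exact test, adjusted p = 0.0212 over both directions of 208 families) as were xyloglucan endotransglucosylase/hydrolases (4 of 17, adjusted p = 0.0392). Major facilitator transporters (8 of 92, adjusted p = 0.0212) and MATE efflux proteins (5 of 37, adjusted p = 0.0375) were in excess among lower genes. Fisher's test takes genes as independent, so these p-values neither allow for correlation between genes nor measure the spread between libraries. XTH4 and XTH8 were also counted in the cell wall loosening list.

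Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes as the 670 of the genotype split, the genotype split itself, and the highest other gave 3. With 35 splits, none can rank better than 1 of 35. Each other split mixes genotypes on both sides, which widens the spread there, so few calls were likely in advance. The count alone therefore does not exclude chance, nor any other difference that goes with genotype.

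The first pattern is the rise of KNAT1, STM, KNAT6 and 3 of 8 xylem markers in DLK2-OE1, highest in replicates 1 and 2, while 3 of 4 shoot apex and flower markers had negative fold changes. In replicates 1 and 2 cell cycle genes also stood highest and light harvesting genes lowest. A lower share of mesophyll would lower the light harvesting genes. If it raised the markers of all other cell types alike, xylem and phloem markers would move together. Their medians were 1.68 and -0.29 (exact permutation p = 0.00288, 8 and 9 genes). The xylem markers had an estimated correlation of 0.83, so they do not count as independent. A loss of mesophyll with unequal gains of other cell types was not tested. A single further tissue mixed in would hold its genes in 1 ratio between libraries, and for 52 genes near 0 in WT the SD of log2(replicate 4 / replicate 3) was 0.95, and from 0.67 to 1.1 over all DLK2-OE1 pairs, in a test rewritten before its value was computed, whose versions disagree: the bound first planned, simulated from counting error and WT spread, was 0.73, and the bound put in its place, the largest SD of a WT pair at matching counts, was 1.01, so this explanation stays open. Several further tissues, such as young stem taken with the rosette, may also account for it and cannot be told apart from an effect of DLK2 on these genes, because both go with genotype. Within DLK2-OE1 replicates 1 to 4, DLK2 was at 120, 150, 137 and 145 CPM. The xylem markers' median there was 1.91, 2.71, 0.97 and 0.54 log2 units above the WT mean. In FPKM, DLK2 was at 115.7, 160.8, 120.2 and 123.2. Replicate 1 had the least DLK2 on either scale but a higher xylem median than replicates 3 and 4. Replicate 2 was highest in both DLK2 and xylem median. In FPKM replicates 1, 3 and 4 were close, so these libraries do not settle whether the spread between replicates followed DLK2 level. That 13 of 15 knotted and secondary wall genes were higher in every DLK2-OE1 library than in any WT library restates the pattern, since these genes were listed after it was seen.

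The second pattern, the copper-linked change, was not in DLK2-OE1 replicates 1 and 2 alone for CSD1, CSD2 and CCS, since without them the median log2 fold change was 1.06, with all 3 above the WT range in each remaining library. On these fewer libraries edgeR gave log2 fold changes of 1.06 for CSD1 (SE 0.21, adjusted p = 0.0892), 1.88 for CSD2 (SE 0.32, 0.084) and -1.50 for COPT2 (SE 0.31, 0.086), which no longer passed, and 0.98 for CCS (SE 0.15, 0.0469), which did. A higher copper supply to the DLK2-OE1 plants may account for it, but the data do not decide: over all members, those that prompted the lists included, targets and deficiency genes had medians of 1.57 and -0.58 (exact permutation p = 0.00352). Without those members and the secondary wall genes the medians were 0.98 and -0.39 (exact permutation p = 0.0476, 4 and 5 genes), an exclusion chosen when the values of each gene were known. An effect of DLK2 on copper handling would give the same values and stays open, untested.

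The third pattern is lower FT, LNK1 and CDF1. A harvest later in the day could lower morning genes and raise evening genes. Morning-phase genes had a median log2 fold change of -0.61 and evening-phase genes of 0.00 (7 each, exact permutation p = 0.0583), which decides nothing. LNK1 and CDF1, which prompted the pattern, are among the 7 morning-phase genes and were not left out. Of the evening-phase genes, 4 had positive and 3 negative fold changes. Among them ELF4 at -0.70 and GI at -0.38 were lower in every DLK2-OE1 library, neither past the threshold, and BOA was at 0.61. FT is in neither list, so these values do not bear on it. A harvest time difference cannot be told apart from an effect of DLK2 on the clock with these values.

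Of 177 tested loci with names of the kind StringTie gives, 3 passed. MSTRG.4878 had 55, 71, 84 and 80 counts in WT and 3, 1, 3 and 0 in DLK2-OE1 (edgeR adjusted p = 0.0111), and MSTRG.2737 had 4, 22, 9 and 11 against 154, 142, 188 and 159 (adjusted p = 0.0111). MSTRG.13195 was lower at a log2 fold change of -1.28 (SE 0.20, adjusted p = 0.0208). These loci were chosen after their values were seen, and their positions are not used here, so their counts do not tell a regulated gene from inserted or rearranged sequence.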
